A study of Homo sapiens with 10 samples.

How the data were processed

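ATAC-seq peak lists of 10 libraries from DLD-1 cells were analysed, 1 list per library, in 4 groups of 2, 2, 3 and 3 libraries taken from the sample labels. Nuclei and libraries were made with a commercial ATAC-seq kit protocol, per the labels' protocols, and the genome build was hg38, per the submitters' processing notes. The aligner and the peak caller are not given in the sources used here. The names of the lists carry tags for trimming, removal of duplicates and mitochondrial reads, a shift for the transposase offset, a limit of 300000 peaks per library and a last filter, as far as the tags say, and these steps could not be checked. Each deposited list is in narrowPeak format, with several summits allowed per interval, and was called per library. Per peak, the authors deposited a fold enrichment over background, which is a linear ratio, a −log10 p, a −log10 q and an integer score, and these are the authors' own values for that peak in that library. The deposited −log10 p values begin at 2, which corresponds to an author p threshold of 0.01. The deposited lists were long, and the number of mapped reads is not used here, so depth is unknown and no counting error can be given.

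Peaks of standard chromosomes that share an interval were joined into 1 region per interval, and regions were ranked within each library by the authors' −log10 p. Because ranks in lists of different length are not comparable, every list was shortened to 141087 regions, the length of the shortest. The value tested is the log2 of 141088 divided by the rank, so a positive change means a rank nearer the top, and a region missing from a shortened list was given rank 141088. Tested regions were the merged union (overlap of at least 1 base) of the 50000 strongest regions per library, kept where they were among the 50000 strongest in every library of at least 1 group. This left 63423 of 72963 regions. Ranks within a list are relative, so a change shared by all regions cannot be seen.

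Regions were tested with limma 3.58.1 in R 4.3.3, with 1 mean per group over all 10 libraries, moderated variances with a trend, and Benjamini-Hochberg adjustment at 0.05. All groups shared 1 estimate of the spread because 2 groups have only 2 libraries. The contrasts were doxycycline against DMSO in iAPC cells (APC restoration), cobimetinib against DMSO in DLD-1 cells, the difference between those 2 changes, and iAPC DMSO against DLD-1 DMSO. No doxycycline treatment of cells without the construct was analysed here. Regions gained or lost outright were those among the 50000 strongest in every library of 1 group and absent from every shortened list of the other. Numbers per library were compared with two-sided exact permutation tests, and overlaps with Fisher's exact test. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for the rest.

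The annotation was a table of gene spans (GRCh38.p14) without strand, exons or sequence. A region was assigned to the protein-coding gene whose span holds its summit, or otherwise to the nearest one within 50000 bases, in place of the nearest transcription start site that had been planned. Such an assignment does not show which gene a region controls. Gene ends, within 1000 bases of either end of a gene, stand in for promoters, and counts over the whole APC span and its flanks stand in for counts over its exons. Planned searches for transcription factor motifs need the genome sequence and were not run.

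The lists of genes, 17 in all, were fixed before the data were examined, as were the tests, the alternatives marked as planned and the rule for naming genes. They cover Wnt targets, ERK output, intestinal stem cells, absorptive and secretory differentiation, YAP/TEAD and fetal epithelium, cell cycle, p53 targets and cyclin-dependent kinase inhibitors, epithelial-mesenchymal transition, epithelial junctions, interferon response, receptor kinases, lysosome and autophagy, lipid synthesis, ribosomal proteins as a control, and fibroblast and blood cell markers. Each was tested with camera at a preset correlation of 0.01, adjusted over 17 lists and 2 treatments, and again with an estimated correlation. The difference between the treatments was tested with camera over the 17 lists. By the naming rule, the text gives the 10 largest rises and 10 largest falls per treatment among called regions near a gene whose groups do not overlap, 1 per gene, up to 4 members per list by the smallest p of a region, and APC. For the other 2 contrasts it gives the 5 largest each way, and for the difference between the treatments the groups were allowed to overlap. The mean over the regions of each gene was added after the data were seen, to summarise genes with many regions, and genes named by that mean were chosen after their values were seen. Of 15390 genes with a mean, 3260 were higher and 5018 lower after restoration, and 3235 and 2809 with cobimetinib.

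The code was tested on simulated lists with known changes. With the restoration libraries it recovered 24.6%, 84.8% and 100% of log2 rank changes of 0.5, 1 and 2 over 49745 regions, with 11 false calls. With changes in the cobimetinib group, 12.3%, 84.8% and 93.8% were recovered over 49605 regions, with 8 false calls. The real groups differ at far more regions, so these false calls do not give the error rate of the real comparisons.

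Alternatives changed 1 choice at a time: the 25000 or 100000 strongest regions, ranking by the authors' fold enrichment, lists shortened to 50000, windows of 500 bases around summits, fits of the 2 groups alone, replicate numbers as a block, a looser filter, ranks without logarithm, robust variances, each library left out in turn, other thresholds and overlaps for outright gains, and other gene assignments. Centring each library on its median, leaving out restored libraries 1 and 2 together, the mean per gene and assignment by the nearest gene end were added after the data were seen.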

Results

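Chromatin accessibility was profiled by ATAC-seq, in which a transposase cuts and tags open DNA, in DLD-1 cells, a human colorectal cancer line with a truncated APC protein. APC is a scaffold of the complex that degrades beta-catenin, so its loss leaves Wnt signalling active. The 10 libraries formed 4 groups. DLD-1 cells received the solvent DMSO (2 libraries) or 1.3 µM cobimetinib, an inhibitor of the kinase MEK, for 72 h (2 libraries). DLD-1 iAPC cells, described as the line for APC restoration, received DMSO (3 libraries) or 250 ng/ml doxycycline for 72 h (3 libraries). The series title speaks of organoids whereas the sample labels name DLD-1 cells, and a combination of both treatments, named in the design text, was not analysed here. The question was how far MEK inhibition and APC restoration each changed accessible chromatin.

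Each library came as a list of peaks. The lists held 195784 and 203647 peaks in the DLD-1 DMSO libraries, 241779 and 249141 with cobimetinib, 196793, 207082 and 199373 in the iAPC DMSO libraries, and 299132, 297675 and 266486 after APC restoration. The number of reads behind them is unknown, since the lists hold no counts, so no interval from depth is given. The names of the lists carry tags for a limit of 300000 peaks and a filter, so the lists of restored libraries 1 and 2 may have been cut short. Peaks per library averaged 287764 ± 18442 (SD, n = 3) after restoration against 201083 ± 5353 (SD, n = 3) in its controls, with an exact two-sided permutation p of 0.1, the smallest that 3 against 3 libraries allow. With cobimetinib the mean was 245460 ± 5206 (SD, n = 2) against 199716 ± 5560 (SD, n = 2), with an exact permutation p of 0.333, the smallest that 2 against 2 allow. Restored libraries 1 and 2 stood apart in their median −log10 p per region, 10.9 and 13.1, against 31.4 in restored library 3 and 22.5 to 37.7 elsewhere. Accessibility is therefore given as a region's rank in equally long lists, by the authors' own −log10 p. That value grows with read depth and depends on the background the peaks were called against, so ranks can differ between libraries for either reason. A log2 rank change of 1 means that a region stood 2-fold nearer the top of the list. A region absent from a list counts at its end, so a change against a group without it is a lower bound, and means that include such regions may be too small. Across the 63423 tested regions, the log2 ranks of replicates correlated with r from 0.973 to 0.985, and those of treated and control libraries with r from 0.828 to 0.838 for restoration and from 0.847 to 0.852 for cobimetinib. These correlations are across regions, which are not independent replicates. The labels do not say that replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical.

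The signal over APC itself was examined first, as a check of the labels. APC lies on chromosome 5 from base 112707498 to 112846239 in hg38. The libraries after APC restoration had 21, 26 and 29 regions within it, the iAPC DMSO libraries 12, 14 and 13, the DLD-1 DMSO libraries 11 and 12, and the cobimetinib libraries 10 and 10. In lists of equal length the counts were 20, 21 and 18 after restoration against 10 to 13 in the other 7 libraries. Within 50000 bases on either side of the gene, every library had 7 to 11 regions. Of the regions found in all 3 restored libraries and in no other library, 8 lay within APC, between bases 112801214 and 112840098. The widest spanned 1500 bases from 112837554 to 112839053. Regions inside APC that were tested across libraries numbered 4, with a median change of −0.16 ± 0.84 (SE) in log2 rank after restoration. The region with the smallest p, which also had the largest rise, lay from base 112818915 to 112819398. This region stood at ranks 19501 to 21765 in the restored libraries. It was absent from the equally long lists of iAPC DMSO libraries 1 and 2 and at rank 135088 in library 3, so its rise was at least 2.74 in log2 rank. It was absent from those of all 4 DLD-1 libraries too, so no change with cobimetinib can be given.

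**Figure D1:**
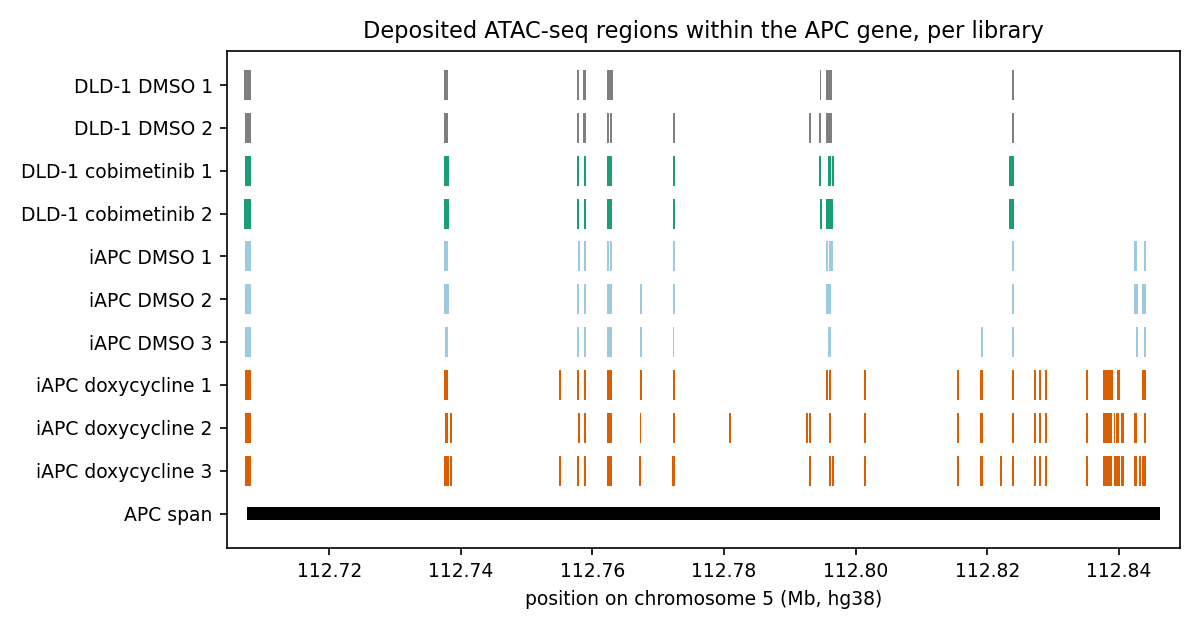
Regions within APC on chromosome 5 in each of the 10 libraries, with the position in Mb on the horizontal axis and 1 line of bars per library. Regions that lie wholly outside the gene are not drawn. The 3 restored libraries hold 21 to 29 regions within the gene and the other 7 hold 10 to 14.

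After APC restoration, more regions near Wnt target genes fell than rose. Averaged over the regions of each gene, ranks fell at WIF1, NOTUM and ZNRF3, which encode inhibitors of Wnt signalling, at NKD1, a feedback inhibitor of Dishevelled, and at FGF18. The log2 change was −0.95 ± 0.05 (SE, 3 against 3 libraries) for ZNRF3, with 12 of its 15 regions lower, and −1.32 ± 0.10 for NKD1, with 7 of 7 lower. It was −1.62 ± 0.10 for WIF1 and −1.61 ± 0.11 for FGF18, each with 2 of 2 regions lower. For NOTUM, with 1 of 2 lower, it was −1.24 ± 0.09. MYC, a growth regulator, fell by 0.54 ± 0.08. Of the 212 regions near 36 Wnt target genes, 107 fell, 39 rose and 66 did not pass, the same counts as those adjusted over the list alone. By gene mean, 20 of the 36 genes fell and 4 rose. The list as a whole ranked lower than other regions by limma's camera test (adjusted p = 0.0468), and the call is lost with adjusted p = 0.0537 with an estimated correlation. Of the 136 regions near intestinal stem cell genes, 76 fell and 25 rose (77 and 26 adjusted over the list alone), with camera adjusted p = 0.0187, and with adjusted p = 0.0537 with an estimated correlation. The 2 lists share members, among them ZNRF3, AXIN2 and LGR5. EPHB2 fell by 0.51 ± 0.09, SMOC2 by 0.56 ± 0.08 and the transcription factor gene SOX9 by 0.41 ± 0.10, whereas PROM1 rose by 0.98 ± 0.09. Ranking regions by fold enrichment ended the calls of MYC, EPHB2 and SOX9. The call of MYC was also lost with the 100000 strongest regions, and that of SOX9 with the 25000 strongest, in lists shortened to 50000 and without restored libraries 1 and 2. Both list calls were lost when regions were ranked by fold enrichment (adjusted p = 0.781) or limited to gene ends (adjusted p = 0.198), and with the mean per gene (0.0613 and 0.0777). The Wnt call was also lost with replicate numbers as a block (0.0522) and in several fits that left out 1 library. Its adjusted p was 0.0518 and 0.0523 without DLD-1 DMSO libraries 1 and 2, 0.0545 and 0.0548 without cobimetinib libraries 1 and 2, 0.0561 without iAPC DMSO library 1, and 0.0734 and 0.0511 without restored libraries 1 and 3.

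Single regions within a Wnt target gene moved apart. At AXIN2, a feedback gene of the pathway, 10 of 15 regions fell and 2 rose, and the region from 65537240 to 65538604 on chromosome 17 rose by 3.27 ± 0.18, from ranks 26572 to 30046 in the controls to 2551 to 3454. The gene mean of AXIN2 was −0.19 ± 0.06 (limma adjusted p = 0.0253), but it was 0.23 with regions within 10000 bases alone (adjusted p = 0.00850), 0.51 with the 25000 strongest (0.00814) and 0.07 under ranking by fold. It did not pass in lists shortened to 50000 (−0.03), with libraries centred (−0.13), without restored libraries 1 and 2 together (−0.17), or without iAPC DMSO library 1 or 2 (−0.17 and −0.18) or restored library 1 or 2 (−0.18 and −0.19). At LGR5, a stem cell receptor, 3 of 7 regions rose and 3 fell, and the gene mean of 0.14 ± 0.06 did not pass (limma adjusted p = 0.0872), though it passed without restored library 1, at 0.18, and was 0.08 without restored library 3. Its region from 71581182 to 71581676 on chromosome 12 rose by 3.21 ± 0.12. A region 27714 bases from NKD1, from 50520467 to 50521044 on chromosome 16, was absent from the equally long lists of all 3 restored libraries, so its change of −2.39 is the least possible fall. At RNF43, which encodes a ligase that removes Wnt receptors, the region from 58402058 to 58402410 on chromosome 17 fell by 1.89 ± 0.11, and the gene mean fell by 0.72 ± 0.08 but was 0.79 under ranking by fold, a call in the opposite direction (adjusted p = 0.00240). Among Wnt targets that rose were LRP4, by 0.91 ± 0.13 at its 1 region, and APCDD1, by 0.73 ± 0.10. Ranking by fold turned both, to −0.11 and −0.26.

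Regions near genes of absorptive differentiation rose more often than they fell after restoration, 52 against 41 of 134 (the same adjusted over the list alone), though the list did not pass (camera adjusted p = 0.344). ISX, an intestinal homeobox gene, rose by 1.06 ± 0.08, and GUCA2B, which encodes uroguanylin, by 1.16 ± 0.10. HNF4A, a transcription factor gene of enterocytes, rose by 0.55 ± 0.12 (0.48, not passing, without restored libraries 1 and 2), and its region from 44435592 to 44436129 on chromosome 20, absent from the equally long lists of all 3 controls, by at least 1.96. LGALS4, with 1 region, rose by 2.53 ± 0.25 but was −1.20 under ranking by fold, a call in the opposite direction (adjusted p = 0.0229). CDX1, also an intestinal transcription factor gene, fell by 1.25 ± 0.11, and a region 1808 bases from it by 3.08 ± 0.17. In the secretory list, where 18 of 64 regions rose and 23 fell (adjusted p = 0.986, with a mean and median below 0 and a test direction above other regions), the single region of ATOH1, the gene that sets secretory fate, rose by at least 1.75, being absent from the control lists of equal length. Of 221 regions near YAP/TEAD and fetal epithelium genes, 104 fell and 39 rose (106 and 39 adjusted over the list alone), and this list did not pass either (adjusted p = 0.124, and adjusted p = 0.0537 with an estimated correlation). TEAD1 fell by 0.56 ± 0.05, with 14 of 20 regions lower, PTPN14 by 0.69 ± 0.06 and CCN1 by 0.66 ± 0.10. The calls of GUCA2B and PTPN14 were lost under ranking by fold, and that of CCN1 with regions within 10000 bases alone.

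The largest single changes after restoration lay near genes of varied function. Among the 10 regions with the largest rise were those nearest to or within AFTPH, GSTK1, SLC5A10, TIAM2, FA2H, TMEM131, WDR11, OTOP3 and CST8. The region near AFTPH had the largest value, 6.79 ± 0.43, but was −0.07 under ranking by fold, and that of OTOP3 was −0.56. The 10 with the largest fall were at GTF2IRD1, AZIN2, ZBTB7C, TH, KYAT1, NKPD1, EPCAM, TOM1L2, RMDN2 and PHF21B. Within GTF2IRD1 the region from 74525776 to 74526368 on chromosome 7 fell by 7.09 ± 0.51, from ranks 38 to 61 to ranks 5147 to 9296. A region 29149 bases from EPCAM, the gene of an epithelial adhesion protein, stood at ranks 63 to 95 in the controls and at ranks 2709 to 3540 after restoration. Of the regions named here, the calls at FA2H and AZIN2 were lost under ranking by fold.

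Genome-wide, 15859 of 63423 regions rose and 20991 fell after restoration by limma with Benjamini-Hochberg adjustment. Changes of at least 2-fold in rank numbered 7096 upwards and 5814 downwards, and 4-fold changes 1461 and 856. Of regions at gene ends 8.49% rose and 26.9% fell, of regions within genes 27.8% and 35.1%, and of regions outside genes 29.4% and 33.8%. Among the 50000 strongest regions of a library, the share at gene ends was 20.8% ± 0.18 (SD, n = 3) against 22.1% ± 0.15 (SD, n = 3), with an exact permutation p of 0.1. The difference of −1.31 percentage points became −2.38 with the 25000 strongest and −2.66 with all regions. Outright, 292 regions among the 50000 strongest in all 3 restored libraries were absent from every control list of equal length, and 185 showed the reverse. Those 2 counts depend on the threshold, from 11 and 17 with the 25000 strongest regions to 21065 and 4595 with all peaks at an authors' −log10 q of at least 2.

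With cobimetinib, more regions near output genes of the ERK pathway, which lies downstream of MEK, fell than rose. EREG, which encodes the EGFR ligand epiregulin, fell by 0.92 ± 0.10 in its gene mean (SE, 2 against 2 libraries), IER3 by 0.79 ± 0.10, and SPRY4 and SPRED1, which encode feedback inhibitors of the pathway, fell by 0.68 ± 0.08 and by 0.74 ± 0.08. The phosphatase gene DUSP6 fell by 0.52 ± 0.11 at its 1 region (−0.31 without cobimetinib library 2), and DUSP5 by 0.66 ± 0.07, though the latter was 0.38 under ranking by fold. HBEGF, another EGFR ligand gene, fell by 0.68 ± 0.11. The calls of SPRED1 and DUSP5 were lost with regions within 10000 bases alone, that of DUSP6 with the 100000 strongest regions, and that of HBEGF with the 25000 strongest and in lists shortened to 50000. Of the 247 regions near 39 such genes, 96 fell, 31 rose and 120 did not pass (98 and 32 adjusted over the list alone), and by gene mean 22 genes fell and 2 rose, DUSP4 by 0.40 ± 0.07 and AREG by 0.31 ± 0.08. The call of DUSP4 was lost within 10000 bases, with the 25000 strongest regions and in lists shortened to 50000. AREG, also an EGFR ligand gene, was −0.37 with regions within 10000 bases alone, a call in the opposite direction (adjusted p = 0.00186), and 0.22, not passing, without cobimetinib library 1. The list ranked lower than other regions (camera adjusted p = 0.00853), and the call is lost with adjusted p = 0.0772 with an estimated correlation. It was also lost under ranking by fold (adjusted p = 0.781), which ended the calls of EREG, IER3, HBEGF and AREG too, and at gene ends alone (adjusted p = 0.506).

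Other fixed lists did not pass with cobimetinib. Of the 221 YAP/TEAD and fetal regions, 78 fell and 36 rose (81 and 38 adjusted over the list alone; adjusted p = 0.183, and adjusted p = 0.0639 with an estimated correlation). In that list the receptor kinase gene AXL fell by 1.52 ± 0.12 at its 1 region, ANXA3 by 0.70 ± 0.08 and the keratin gene KRT7 by 0.75 ± 0.13, while FJX1 rose by 0.88 ± 0.08 (−0.02 with the 25000 strongest regions). The call of FJX1 was lost with the 100000 strongest and in lists shortened to 50000 too. FN1, the fibronectin gene, fell by 0.75 ± 0.07 with 8 of 8 regions lower, and TGFBI by 0.86 ± 0.08 with 10 of 12 lower. IRS1, an adaptor of insulin receptor signalling, fell by 0.97 ± 0.08 and FGFR2 rose by 0.61 ± 0.08. The calls of KRT7, FN1 and FGFR2 were lost under ranking by fold. Wnt target regions were split, 51 higher and 52 lower of 212 (adjusted p = 0.986), and so were stem cell regions, 36 and 36 of 136 (adjusted p = 0.986). By gene mean, 8 Wnt target genes rose and 7 fell, and 3 stem cell genes rose and 2 fell. The regions of EPHB2 from 22831846 to 22832757 on chromosome 1 and of SMOC2 from 168637776 to 168638236 on chromosome 6 fell by 5.20 ± 0.51 and 3.88 ± 0.30. A region 205 bases from MYC, from 127742887 to 127743335 on chromosome 8, fell by 1.72 ± 0.14.

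**Figure D2:**
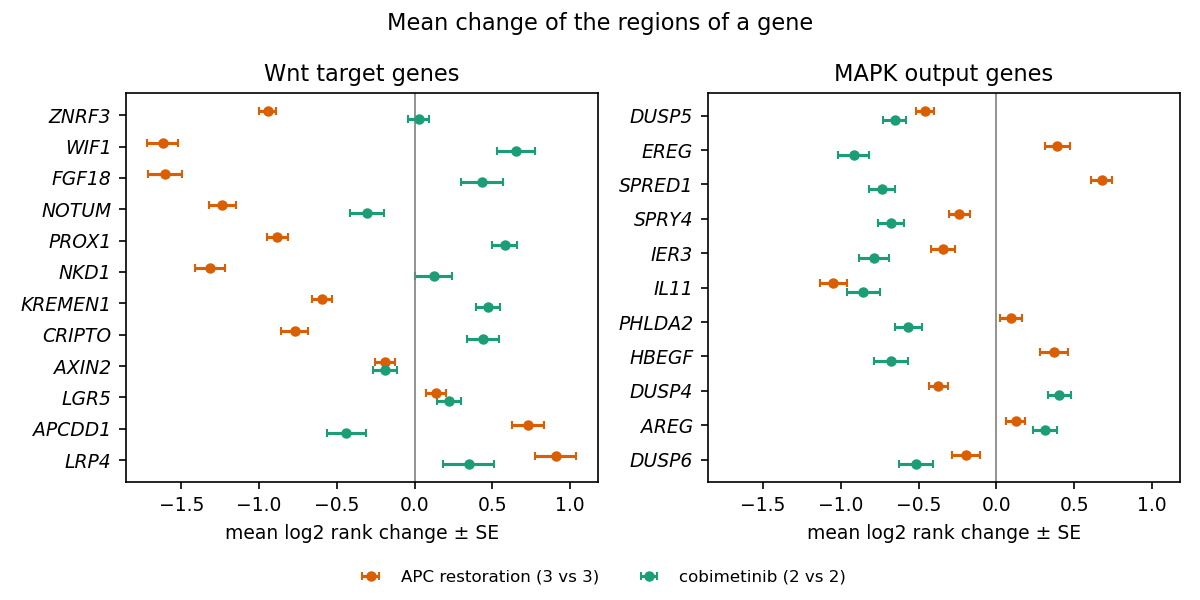
Mean log2 rank change over the regions of selected Wnt target genes (left) and ERK output genes (right) after APC restoration (3 against 3 libraries) and with cobimetinib (2 against 2), points with standard errors. The Wnt genes drawn had the smallest p of the gene mean after restoration, and the ERK genes the smallest p with cobimetinib. Further members named in the text were added. Each panel was thus chosen by 1 treatment and cannot show that a list differs between the treatments. ZNRF3 fell by 0.95 after restoration, and EREG fell by 0.92 with cobimetinib.

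The 10 largest rises with cobimetinib were at SLC24A2, ART5, CTLA4, YAF2, LTBP1, AFF4, TIMM17A, LRP2, GPRIN2 and PLD1. Within SLC24A2 the region from 19960112 to 19961023 on chromosome 9 rose by 6.46 ± 0.31, from ranks 10834 and 10918 to ranks 187 and 82. A region 26469 bases from CTLA4 rose by 4.82 ± 0.12, and that of LRP2 was −0.65 under ranking by fold, which also ended the calls at SLC24A2, ART5, LTBP1, TIMM17A and GPRIN2. The 10 largest falls were at TRERF1, EML6, PLCB1, NAP1L4, CDC42BPB, TALDO1, STARD13, NSMCE1, NINL and PAX8. The region within TRERF1 from 42338125 to 42339254 on chromosome 6 fell by 6.80 ± 0.69, from ranks 80 and 99 to ranks 9884 and 9984. Of these 10, ranking by fold ended the calls at NAP1L4 and NSMCE1. In all, 14636 regions rose and 15498 fell by limma, 5770 and 6370 of them by at least 2-fold. Of regions at gene ends 12.8% rose and 7.88% fell, of those within genes 25.8% and 27.1%, and of those outside 24.8% and 29.0%. The share of gene ends among the 50000 strongest regions was 21.6% ± 0.04 (SD, n = 2) against 21.8% ± 0.14 (SD, n = 2), an exact permutation p of 0.333, and the sign of this difference turned with the 25000 strongest. It was −0.22 percentage points, and −1.95 with all regions. Outright gains and losses numbered 269 and 165 regions, from 11 and 10 with the 25000 strongest to 25949 and 7314 with all peaks at an authors' −log10 q of at least 2. Without cobimetinib library 2 the losses were 251.

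The remaining tests of lists did not pass, and the counts adjusted over the list alone differed from those given here by at most 2 regions. After restoration, 50 ERK output regions rose and 96 fell of 247 (adjusted p = 0.679), while ETV1, a transcription factor gene of that list, rose by 1.28 ± 0.10. Cell cycle regions numbered 13 higher and 26 lower of 72 (adjusted p = 0.679), p53 target and kinase inhibitor regions 9 and 16 of 44 (0.876), epithelial-mesenchymal transition regions 20 and 41 of 91 (0.489), and junction regions 35 and 77 of 177 (0.489). Among the last, CLDN2, a claudin gene, fell by 1.12 ± 0.07 with 5 of 5 regions lower. Interferon regions numbered 10 and 22 of 59 (0.679), receptor kinase regions 32 and 51 of 141 (0.877), lysosome and autophagy regions 21 and 33 of 95 (0.986), lipid synthesis regions 13 and 25 of 80 (0.857), and ribosomal protein regions 7 and 16 of 59 (0.679). Markers of other cell types numbered 11 and 17 of 47 for fibroblasts (0.724) and 6 and 8 of 34 for blood cells (0.986). With cobimetinib the absorptive list had 25 regions higher and 30 lower of 134 (adjusted p = 0.926), the secretory list 16 and 17 of 64 (0.986), the cell cycle list 9 and 16 of 72 (0.986) and the p53 list 5 and 8 of 44 (0.679). Transition regions numbered 20 and 37 of 91 (0.668), junction regions 24 and 55 of 177 (0.243), interferon regions 19 and 10 of 59 (0.679) and receptor kinase regions 31 and 38 of 141 (0.724). Lysosome regions numbered 21 and 17 of 95 (0.986), lipid synthesis regions 14 and 21 of 80 (0.679), ribosomal protein regions 10 and 11 of 59 (0.970), fibroblast regions 11 and 13 of 47 (0.986) and blood cell regions 9 and 13 of 34 (0.986). With cobimetinib the secretory list's mean was −0.05 and its median 0.01. The Wnt and lysosome lists had a mean and median below 0 and a test direction above other regions, and the ribosomal protein and fibroblast lists the opposite.

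Some genes moved the same way with both treatments and others in opposite directions. TGFBI, an extracellular matrix gene, fell by 0.86 ± 0.07 after restoration and by 0.86 ± 0.08 with cobimetinib, and CLDN2 fell by 1.12 ± 0.07 and 0.73 ± 0.09. SPRED1 rose by 0.68 ± 0.07 after restoration and fell by 0.74 ± 0.08 with cobimetinib. In the same order PROX1 changed by −0.88 ± 0.07 and 0.58 ± 0.08, and WIF1 by −1.62 ± 0.10 and 0.65 ± 0.12. With cobimetinib, the calls of CLDN2 and WIF1 were lost under ranking by fold, that of WIF1 also with the 100000 strongest regions and in 500-base windows, and that of PROX1 within 10000 bases and with the 25000 strongest. Regions higher in both numbered 4894, against 3660 expected from independent lists (Fisher's exact odds ratio 1.73), and regions lower in both 6213 against 5129 (odds ratio 1.501). Opposite calls numbered 4214 against 3875 for higher after restoration and lower with cobimetinib, and 4498 against 4844 for the reverse. Among changes of at least 2-fold, regions higher in both numbered 1018 against 646 expected and lower in both 1191 against 584. The excess of regions higher after restoration and lower with cobimetinib turned there, with 649 against 713 (odds ratio 0.89). The reverse, already below its expected number over all sizes, counted 525 against 529. Of the 19819 regions called in both, 56.0% moved the same way, and the changes correlated with r = 0.103 and rho = 0.082 across regions. The comparisons share no libraries.

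**Figure D3:**
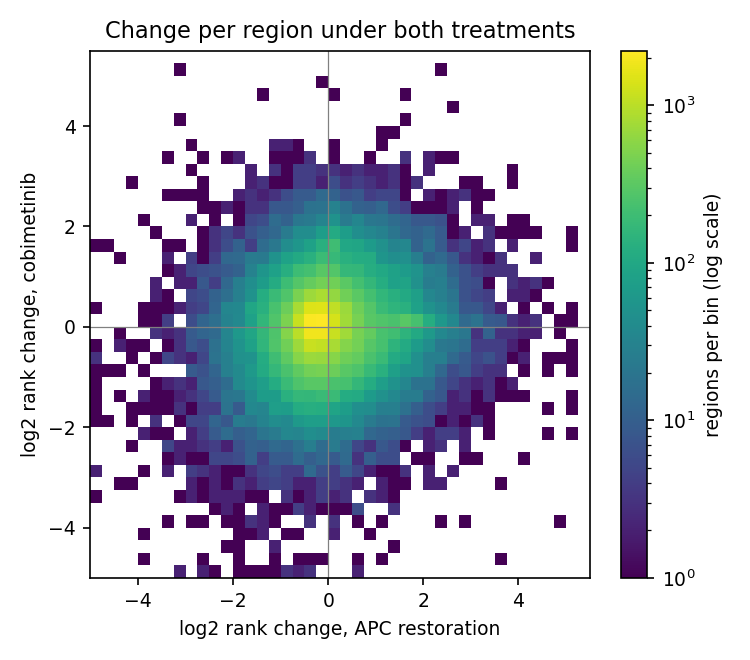
Log2 rank change after APC restoration (horizontal axis) and with cobimetinib (vertical axis) for the 63423 tested regions, as the number of regions per square on a log colour scale. The changes correlated with r = 0.103 across regions.

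The test of the difference between the treatments, each against its own DMSO libraries, called 34073 regions, 16043 with the higher change after restoration and 18030 with the higher change with cobimetinib. The largest differences in favour of restoration were at AFTPH, MAGI2, SLC5A10, MTPAP and DOCK9, and those in favour of cobimetinib at SLC24A2, TH, LRP2, MRPL52 and GTF2IRD1. The region of SLC24A2 differed by −9.67 ± 0.40, having moved from ranks 8041 to 10412 to ranks 79018 to 90021 after restoration. That of MAGI2, from 77989793 to 77990620 on chromosome 7, differed by 8.74 ± 0.60. Ranking by fold ended the calls at MAGI2, DOCK9, LRP2 and GTF2IRD1. As lists, the Wnt targets differed by −0.30 (camera adjusted p = 0.253), the stem cell genes by −0.31 (0.253), the ERK output genes by 0.25 (0.263) and the absorptive genes by 0.23 (0.382), and none of the 17 lists passed.

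The DMSO groups of the iAPC line and of DLD-1 were compared to show how far regions differ with no treatment. The 5 regions that stood highest in iAPC cells were at PGK1, WEE1, KLK4, LMLN and MYO15B, and those lowest at NBPF1, SLC4A8, NUAK2, DUSP8 and FBLN2. NBPF1 belongs to a family of near-identical copies, so its reads can be shared between them. The region 107 bases from PGK1, the gene of a glycolytic enzyme whose promoter is widely used in expression vectors, from 78103747 to 78104385 on the X chromosome, had rank 10 in all 3 iAPC DMSO libraries, ranks 6 to 12 after restoration and ranks 5817 to 13043 in the 4 DLD-1 libraries, a change of 9.36 ± 0.62 between the DMSO groups. Its authors' fold enrichment was 24.3 to 25.2 in iAPC DMSO and 21.6 to 23.3 in DLD-1 DMSO. Ranking by fold turned the changes of PGK1, WEE1 and KLK4, to −0.68, −0.06 and −0.19, and ended the calls at MYO15B and NUAK2. In all, 14992 regions were higher in iAPC DMSO libraries and 15135 lower, about as many as with cobimetinib, and 3753 and 3868 differed by at least 2-fold. The labels name no batch that holds both lines, so the line and any batch cannot be told apart.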

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

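The 10 splits of the iAPC libraries, the comparison of restored library 3 with libraries 1 and 2 and the count of genes with as many restoration-specific regions as APC were tests chosen only after the results were seen.

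The change in rank differed between APC restoration and cobimetinib at 34073 of 63423 regions by the limma test of the difference itself, which is why it stands here. The treatments and the lines differ together. At SLC24A2, for example, ranks of 8041 to 10412 in the iAPC controls became 79018 to 90021 after restoration, and ranks of 10834 and 10918 in the DLD-1 controls became 187 and 82 with cobimetinib.

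After APC restoration 36850 regions changed. Of the 10 splits of the 6 iAPC libraries, 1 (the real one) gave that many and the highest other gave 0 by limma. The others had 660 to 1094 regions at an unadjusted p under 0.05. Every other split put restored and control libraries in the same group, which widens the spread within groups. Their low counts therefore do not show what a grouping without a treatment effect gives, and 10 splits are too few for a share under 0.05. Restored libraries 1 and 2 had low median peak scores, though their scores at rank 50000 lay within the range of the unrestored libraries. Those low medians are argued against as the cause. The changes measured with library 3 and with libraries 1 and 2 correlated with r = 0.917 across regions, with no control library in common. Gain or loss of long stretches of chromosome is argued against as the main cause, since 10-Mb bins held 1.94% of the variance of the change. With the changes shuffled over regions the bins held at most 0.58%, and the bin medians ran from −0.30 to 0.28. Smaller gains or losses of a stretch therefore cannot be excluded. The longer peak lists of the restored libraries may still contribute, and shortening the lists to 50000 could not decide this. Of the called regions, 89.1% kept their direction there and 10.9% tied at the end of the lists. Shortening cuts off the same ranks, so it makes ties and can hardly turn a direction. An effect of doxycycline itself, apart from APC, was not tested and stays open beside an effect of APC.

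The signal over APC stood apart after doxycycline, and that next to PGK1 between the lines. Copies of the chromosome around PGK1 are argued against, because the 13 other regions within 500000 bases had a median change of 0.053 ± 0.139 (SE) between the DMSO groups. For APC, the 22 regions within 500000 bases outside the gene had a median change of 0.47 ± 0.35 after restoration, so a copy gain of the surroundings cannot be told apart from none. That the inducible construct carries APC sequence is a candidate explanation. All 3 restored libraries and no other held 8 regions of APC, and 0.103% of the 3869 protein-coding genes of like length had as many. The iAPC DMSO libraries come from the same line, so this count cannot tell construct sequence from a change at the gene itself. All 3 iAPC DMSO libraries and no DLD-1 library held 2 regions of APC, and 4.88% of those genes had as many. The construct explanation is a hypothesis found and tested on the same data, and the sequence of the construct was not used here.

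The DMSO groups of the iAPC line and of DLD-1 differed at 14992 and 15135 regions. Copy number over long stretches could not account for most of this, since 10-Mb bins held 2.25% of the variance of the change. With the changes shuffled they held at most 0.55%, and bin medians ran from −0.28 to 0.30, so smaller copy differences cannot be excluded. A difference between the lines, as the design names it, and a difference between batches cannot be told apart, because the labels name no batch that holds both lines. For cobimetinib the same bins held 1.205% of the variance, against at most 0.61% with the changes shuffled.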

How the results depend on the processing

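Centring each library, leaving out restored libraries 1 and 2 together, the mean per gene and assignment by the nearest gene end were chosen after seeing the data, and the motif alternatives could not be run without a genome. Counts of changed regions moved by more than 1.5 times only with the number of regions tested. With the 25000 strongest regions they were 7296 higher and 10091 lower after restoration, 6896 and 7914 with cobimetinib, 16367 for the difference between the treatments and 16094 between the DMSO groups. With the 100000 strongest they were 30872, 36977, 28011, 26419, 65805 and 48753 in that order, set by the number tested. Under the other alternatives, each library left out included, they stayed within 1.5 times. A like count does not mean that the same regions were called. Without 1 library they ran from 14627 to 15787 and from 18794 to 20998 for restoration, 12060 to 14961 and 12811 to 15860 for cobimetinib, 30342 to 33669 for the difference and 22585 to 30895 for the DMSO groups. Where this left 1 library in a group, it was assumed to vary like the other groups. Without restored libraries 1 and 2 the restoration counts were 13293 and 14823.

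Outright gains and losses depend on the threshold by construction. They were 11 and 17 after restoration and 11 and 10 with cobimetinib for the 25000 strongest regions. They were 184 and 53 (restoration) and 232 and 86 (cobimetinib) where absence from the full lists was required, and 5932, 5130, 5700 and 5596 where absence from the 50000 strongest was enough. They were 21065, 4595, 25949 and 7314 at a −log10 q of at least 2 and 17762, 4452, 21418 and 6655 at 5. Without 1 library they ran from 338 to 364, 203 to 218, 373 to 381 and 209 to 251, since fewer libraries must share a region. The lower share of gene ends with cobimetinib turned to 0.506 percentage points with the 25000 strongest (exact permutation p = 0.667, range of the alternatives −1.95 to 0.506), and the cause was not tested. The difference after restoration ran from −2.66 to −1.31. Without 1 library these differences ran from −1.42 to −1.26 for restoration and from −0.316 to −0.124 for cobimetinib, and the differences in peaks per library from 80998 to 97321 and from 41813 to 49676. Of regions called in both treatments, 52.9% to 64.0% moved the same way over the alternatives and 55.7% to 57.2% without 1 library.

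Of 578 alternatives of the list tests, 557 kept their side of 0.05, most with no call to lose, and none reversed. All 19 losses hit the 3 calls. The Wnt call after restoration was lost with an estimated correlation (adjusted p = 0.0537), at gene ends (0.198), under ranking by fold (0.781), with the mean per gene (0.0613) and with the replicate block (0.0522), with 0.0392 to 0.0734 without 1 library. The stem cell call was lost in the first 3 of these (0.0537, 0.198, 0.781) and with the mean per gene (0.0777), with 0.0157 to 0.0289 without 1 library. Both lists ran from 0.0113 to 0.781 over the alternatives. The ERK call with cobimetinib was lost with an estimated correlation (0.0772), at gene ends (0.506) and under ranking by fold (0.781), with 0.00333 to 0.0243 without 1 library and 3.46e-05 to 0.781 over the alternatives. YAP/TEAD and fetal genes passed after restoration within 10000 bases (0.0345) and with cobimetinib by the mean per gene (0.0406). The cause was not tested.

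Of 2684 alternatives of 137 values of named genes and regions, 2603 kept direction and side of the threshold, and 30 lost their call with the same direction under ranking by fold. That ranking gave no value for 5 of them (TH in 2 comparisons, regions of RNF43 and ERBB2, and DUSP6), the 25000 strongest regions gave none for 10, and 500-base windows none for AXL, absent there from all DLD-1 lists. That ranking reversed AFTPH (−0.070), OTOP3 (−0.56), RNF43 (0.79), LGALS4 (−1.20), AXIN2 (0.072), APCDD1 (−0.26) and LRP4 (−0.11) after restoration, LRP2 (−0.65), CDK1 (−0.041), IRF1 (−1.16) and DUSP5 (0.38) with cobimetinib, and PGK1 (−0.68), WEE1 (−0.059) and KLK4 (−0.19) between the DMSO groups. Of these 14, RNF43 (adjusted p = 0.00240), LGALS4 (0.0229) and IRF1 (0.00382) passed in the opposite direction and the other 11 did not pass. Over all regions, changes by both rankings correlated with r = 0.697 (restoration), 0.676 (cobimetinib), 0.683 (difference) and 0.559 (DMSO groups), with the same direction in 90.0% to 91.1% of called regions. Regions within 10000 bases reversed AXIN2 (0.23) and AREG (−0.37), both passing, the 25000 strongest AXIN2 (0.51, passing) and FJX1 (−0.017), and the 100000 strongest LRP4 (−0.022), where the set of regions averaged differs by construction. Without restored libraries 1 and 2, the calls of SOX9, AXIN2 and HNF4A were lost.

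Replicate numbers did not pair the samples. Deviations of same-numbered iAPC libraries correlated with r = 0.046, 0.054 and 0.028 across regions. Each was its library's best match, a hint from the data and not the design. In DLD-1 the value was −0.075. With the replicate block, the counts were 15776 and 20821, 14472 and 15378, 33741 and 28173. Read depth is unknown, so no limit from depth can be given.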

Other observations

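No test in this part was weighed as an explanation, and the genes are those that the fixed lists and the rule for naming genes gave. Regions of receptor kinase genes moved in opposite directions after APC restoration. Within ERBB2, the region from 39704573 to 39705118 on chromosome 17 rose by 2.01 ± 0.12 (SE, 3 against 3 libraries), and regions within ERBB3 and EGFR rose by 1.88 ± 0.15 and 1.52 ± 0.11, while a region within IGF1R, from 98776519 to 98777345 on chromosome 15, fell by 2.80 ± 0.16. Among lipid synthesis genes, a region near DHCR7, the gene of the last step of cholesterol synthesis, fell by 3.42 ± 0.23, and 1 within the fatty acid elongase gene ELOVL6 rose by 1.85 ± 0.10. Within TFEB, the gene of a regulator of lysosome genes, a region rose by 2.17 ± 0.10. A region near MMP9, a matrix protease gene, rose by 4.25 ± 0.24. All of these passed limma's test, and their lists did not.

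With cobimetinib the cell cycle list did not pass, with 9 regions higher and 16 lower of 72, and its members moved both ways. The region within CCNB2, which encodes cyclin B2, from 59124061 to 59124683 on chromosome 15, rose by 2.31 ± 0.20 (SE, 2 against 2 libraries) and also after restoration, by 1.64 ± 0.16, a call lost under ranking by fold. A region near CDK1, the kinase that drives mitosis, rose by 2.53 ± 0.29 but was −0.04 under ranking by fold, and 1 within MCM5, a replication gene, fell by 2.003 ± 0.186. Near IRF1, an interferon regulator gene, a region rose by 3.07 ± 0.20 but was −1.16 under ranking by fold, a call in the opposite direction (adjusted p = 0.00382). A region near CTSD, the cathepsin D gene, fell by 3.10 ± 0.19. Within SCD, the stearoyl-CoA desaturase gene, a region absent from the equally long DLD-1 DMSO lists rose by at least 1.997, and 1 near INSIG1, a sterol sensor gene, fell by 2.87 ± 0.32. The region within ITGAM, a myeloid integrin gene, rose with both treatments, by 1.79 ± 0.12 after restoration and, being absent from the equally long DLD-1 DMSO lists, by at least 2.85 with cobimetinib.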
